A study of Homo sapiens with 4 samples.

How the data were processed

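RNA was profiled in natural killer (NK) cells, the blood lymphocytes that kill virus-infected and tumour cells without prior sensitisation, from 2 healthy donors. Cells of each donor were kept in normal gravity or in simulated microgravity, a culture condition meant to reduce the net effect of gravity on the cells, which gave 4 libraries. Per the labels' protocols, total RNA was extracted with a column kit and libraries were made with a combined mRNA and miRNA kit, then sequenced as single-end reads on an Illumina NovaSeq. Per the submitters' processing notes, Partek version 10.0.23.0720, cutadapt, Bowtie2, STAR and DESeq2 were used with genome build hg38. The notes as used here give these names without roles or order, and the normalization method and the annotation release are not given in the sources used here.

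Both deposited tables, for genes and for transcripts, hold log2 values that the authors had normalized. The lowest value equals log2 of 0.0001, so 0.0001 had been added before the logarithm. Returned to the linear scale, the gene values summed to between 935791 and 1000661 per library and the transcript values to between 839577 and 974314, so the libraries had similar totals without sharing an exact one. Levels below are these linear values. In the deposited gene table, values under 3 fell near whole multiples of a smallest step, of 0.0235, 0.0186, 0.0214 and 0.0268 in the normal gravity libraries of donors 2 and 3 and the simulated microgravity libraries of donors 2 and 3. If that step is 1 read, a value of 1 stood for 42.6, 53.8, 46.8 and 37.4 reads. Between 35.2% and 51.2% of the low values lay within 0.05 of a whole multiple, so whole counts could not be recovered and no count model was used. A step fixed beforehand would give 10% by chance. The step was chosen to make this share largest, so chance would give more than that. Depth per gene is therefore approximate and no counting interval is given. No per-sample column was left unmapped.

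XIST, TSIX and Y-linked genes were left out before any step. The remaining 11178 genes and 22179 transcripts were filtered to a mean value of at least 1 over the 4 libraries, which left 11122 genes and 22028 transcripts. Of the gene symbols, 10883 were found in the GENCODE 29 annotation of GRCh38 (the same build as hg38), which gave the coordinates; positions are 1-based.

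Groups and donor numbers came from the labels. The main test was limma's moderated test with an intensity trend on the deposited log2 values, simulated microgravity minus normal gravity, 2 libraries against 2, two-sided, with Benjamini-Hochberg adjustment over all features and a threshold of 0.05. Replicates are the 2 donors, so p-values measure the spread between those donors' libraries. The same donor number in both groups means the same donor, so the numbers pair the samples, and a fit with the donor as a block was tried as well. The correlation across genes of same-donor deviations from the group means was -0.024 on the log2(value + 1) scale and -0.002 on the deposited scale. Fold changes of genes listed at or near 0 in any library depend on the 0.0001 that was added, so levels per library are given for those genes. Changes per donor are differences of log2(value + 1), which understate the change of low genes.

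Before the data were examined, 36 gene lists were fixed, covering NK cell functions, cytoskeleton, metabolism, stress and the markers of T, B, monocyte and dendritic, platelet, erythroid, granulocyte and innate lymphoid cells. The 31 lists with 5 or more tested members were tested with camera (preset correlation 0.01), a test of a list against all other genes, with Benjamini-Hochberg adjustment over the lists. Camera with an estimated correlation and fry, a rotation test of whether a list's own genes move on balance in a single direction, were alternatives. Each list also has a count of members past 0.05 with adjustment over the list alone. The rule for naming genes, also fixed beforehand, had 3 parts. The first took the 10 protein-coding genes with the largest change in each direction among those past the threshold with the same sign in both donors, filled, where fewer passed, with the genes whose smaller donor change was largest. The second took 10 NK effector and activation genes whatever their values, of which 5 were among the tested genes. IFNG, FASLG, NCR1, KLRK1 and FCGR3A were not. The third took up to 4 members of each list with the same sign in both donors and the largest change, in the direction of the list where the list was called. Highly polymorphic receptor families and genes commonly deleted in people were never named. Where the text names any other gene, it says that the gene was chosen after its values were seen.

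Alternatives changed the donor block, the low-value filter, the value added before the logarithm, the normalization, the variance model, a fold threshold, the libraries entered and the genes entered. On libraries simulated from the real levels with 200 changed genes, the gene test without a block (10820 genes) recovered 42% of 2-fold, 64% of 4-fold, 92% of 16-fold and 100% of 64-fold changes, and called 4 unchanged genes. With the block it recovered 2%, 28%, 60% and 86%. The transcript test without a block (21565 transcripts) recovered 4%, 12%, 30% and 48% of the same folds, and with the block 0% of each. Noise for all 4 simulated libraries was drawn from the spread between the 2 normal gravity libraries, and each change was equal in both donors. The SD of the real log2(value + 1) differences was 0.28 between those libraries but 1.05 between the simulated microgravity libraries. These recovery rates therefore do not carry over to the real comparison. In a simulated set of 20 lists, camera called the single shifted list and 0 of the others. Those lists held random genes with independent noise, so the simulation does not test the preset correlation. The functions that compare a library with a mixture of 2 profiles returned 70.8% and 30.6% for a simulated mixture of which 30% came from the second profile. R 4.3.3 with limma 3.58.1 and Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9 were used.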

Results

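Messenger RNA levels of human NK cells were compared between normal gravity and simulated microgravity. The study's stated interest is how simulated microgravity lowers the killing of leukaemic cells. There were 2 libraries per group, from donors 2 and 3 of the labels, and each donor gave a library in both groups. Over 11178 genes the median level was 26.5 and 28.2 in the normal gravity libraries of donors 2 and 3 and 27.3 and 24.6 in their simulated microgravity libraries, in the authors' normalized values on the linear scale.

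The 4 libraries were unevenly related. Across genes, which are not independent replicates, the 2 normal gravity libraries had a Pearson correlation of 0.991 on the log2(value + 1) scale, and 93 genes differed between them by at least 2-fold on that scale. The donor 2 pair of normal gravity and simulated microgravity had a correlation of 0.946 with 601 such genes, and the donor 3 pair had 0.747 with 3230. The 2 simulated microgravity libraries had 0.872 with 1868 such genes. Genes of the T and NK lineages differed strongly between libraries. CD3D, a chain of the T cell receptor complex (chromosome 11, 118338954 to 118342744), was listed at 0 and 0.223 in normal gravity (donors 2 and 3) and at 361.5 and 1076 in simulated microgravity. NKG7, a cytotoxic granule protein (chromosome 19, 51371606 to 51372715), was at 2258 and 2202 in normal gravity and at 1444 and 0.947 in simulated microgravity. The donor 3 simulated microgravity library thus listed the NK gene near 0 and the T cell gene at its highest level, and donor 2's lay between that library and the normal gravity libraries for both genes.

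**Figure D1:**
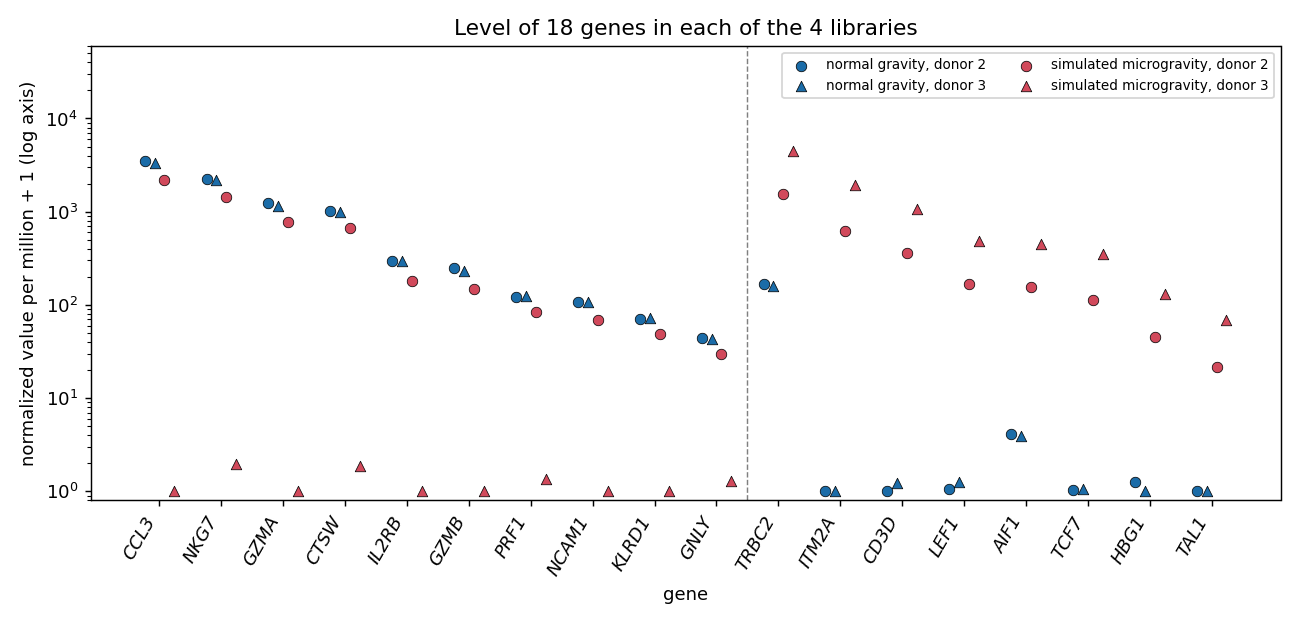
Level of 18 genes in each library, as normalized value plus 1 on a log axis; blue marks normal gravity, red simulated microgravity, circles donor 2 and triangles donor 3. The 10 genes left of the dashed line, among them NKG7, GZMA and PRF1, lie at or below 0.947 before the addition of 1 in the donor 3 simulated microgravity library, and the 8 genes to the right of it, among them CD3D and TAL1, are higher in both simulated microgravity libraries than in normal gravity. The genes drawn were picked from those named by the rule. Named genes outside this split, among them TNFSF10, TRDC and HBD, are not drawn.

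No single gene passed the test between the groups. limma called 0 of 11122 genes at an adjusted p of 0.05, with or without the donor block, while 1275 had an unadjusted p under 0.05, of which 1082 were higher and 193 lower in simulated microgravity. Lists for which no count over the list alone is given below had 0 members past it. Without the donor 2 simulated microgravity library 5967 genes were called (2626 higher, 3341 lower), and without the donor 3 library 569 (363 higher, 206 lower), the lone library being assumed to vary like the other group. Without an intensity trend in the variance model 9 genes were called higher, each listed at 0 in both normal gravity libraries: ITM2A, PRDX2, HMGN3, OAT, HSPB1, CPNE3, GNB4, TAL1 and SLC39A4.

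On the deposited log2 scale, where the 0.0001 that was added puts genes listed at 0 first, the largest increases in both donors were in genes listed at 0 in normal gravity libraries, and none passed. ITM2A, a membrane protein of developing T cells (chromosome X, 79360384 to 79367667), was listed at 0 in both normal gravity libraries and at 615.5 and 1944 in simulated microgravity (donors 2 and 3; limma adjusted p = 0.139). TAL1, a transcription factor of blood stem cells and red cell precursors that is switched on in some T cell leukaemias (chromosome 1, 47216290 to 47232220), was listed at 0 in both and then at 20.5 and 68.6 (adjusted p = 0.324). PRDX2, a peroxide-removing enzyme, was listed at 0 and then at 86.1 and 238.5. HMGN3, a nucleosome-binding protein, reached 57.5 and 193.8, and GNAQ, a G protein alpha subunit, reached 82.3 and 228.3 from 0 and 0.0372. OAT, HSPB1, CPNE3, GNB4 and SLC39A4 completed the 10 genes, with values of 8.24 to 31.8 in donor 2 and 28.0 to 89.2 in donor 3. In the other direction the rule, which ranked genes by the smaller of the 2 donor changes, picked genes of low level. Mean changes were larger in abundant genes that were at 0 in donor 3 simulated microgravity, such as CCL3 (log2 change -12.83). H2AC18, a histone gene with near-identical copies whose reads may not be separable, was at 15.4 and 19.1 in normal gravity and at 3.27 and 0.0278 in simulated microgravity. SEMA7A, a membrane-anchored semaphorin, was at 7.88 and 7.21 in normal gravity and at 3.04 and 0.95 in simulated microgravity (log2 change -2.15, SE 0.68, adjusted p = 0.349). MACC1, S100A9, TMEM63B, AFMID, GDPD3, ZNF625-ZNF20 and 2 unnamed clone genes (AC138894.1 and AC108488.2) made up the rest, at 1.30 to 11.4 in normal gravity.

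Transcripts of the killing machinery were lower as a list in the simulated microgravity libraries, far more in donor 3 than in donor 2. All 14 tested cytotoxic effector genes were below the normal gravity level in both donors, with a median difference of -0.61 in donor 2 and -6.02 in donor 3. GZMB, the protease that starts apoptosis in target cells (chromosome 14, 24630954 to 24634267), was at 248.5 and 229.5 in normal gravity and at 147.8 and 0 in simulated microgravity (donors 2 and 3). PRF1, the pore-forming perforin (chromosome 10, 70597348 to 70602775), was at 119.3 and 122.6 and then at 82.9 and 0.375 (log2 change -4.44, SE 2.70, adjusted p = 0.362). GNLY, a membrane-damaging granule protein, was at 43.2 and 42.6 and then at 28.6 and 0.294. GZMA, the other abundant granzyme, was at 1225 and 1140 and then at 775.6 and 0, and CTSW, a protease of cytotoxic lymphocytes, at 1026 and 1002 and then at 670.7 and 0.882. TNFSF10, the death ligand TRAIL, was at 13.4 and 15.2 and then at 9.17 and 2.14. Camera called the list lower (adjusted p = 0.00998, and 0.0014 with the block), but not with an estimated correlation (adjusted p = 0.759), and 0 of its 14 members passed over all genes or adjusted over the list alone. In the same libraries the T cell gene CD3D stood at 361.5 and 1076. Against a mixture of the normal gravity and donor 3 simulated microgravity profiles, described below, the donor 2 median of the list was -0.04. The lower levels therefore cannot be told apart from a smaller share of NK cell RNA in these libraries. The same limit holds for the receptor, cytokine and cytoskeletal lists that follow.

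Receptors that steer killing were mostly lower, without a list call. Of 24 activating receptors and adaptors on the list 13 were tested, and NCR1, KLRK1 and FCGR3A were not among them. Of these 13, 10 were lower and 3 higher in both donors (medians -0.49 and -1.78, camera adjusted p = 0.103). SLAMF7, an activating receptor, was at 276.5 and 276.2 in normal gravity and at 175.7 and 0 in simulated microgravity, CD244 at 168.2 and 199.7 and then at 116.8 and 0, and TYROBP, the adaptor of several NK receptors, at 105 and 108.3 and then at 59.7 and 0. Among 9 inhibitory receptors 8 were lower in both donors (medians -0.42 and -2.42; adjusted p = 0.108). KLRD1, the CD94 subunit, was at 69.2 and 71.4 and then at 48.3 and 0, and TIGIT at 17.99 and 20.35 and then at 10.3 and 0.0268. LAIR1, a collagen receptor, went the other way, from 0.44 and 1.23 to 14.8 and 47.7. Adjusted over the list alone, 1 member of each list passed, in the higher direction: LAIR1, and CD59, an inhibitor of complement named because it passed. The lytic granule traffic list had 16 of 23 members lower in both donors (medians -0.22 and -0.56; adjusted p = 0.112). Within it STX11, the fusion protein needed for granule release, was at 107.7 and 108.3 and then at 74.9 and 1.26, and RAB27A, which docks granules, at 150.1 and 141.2 and then at 88.7 and 6.76. Of 31 proximal signalling genes 22 were lower in both donors (medians -0.25 and -1; adjusted p = 0.0906), among them SYK at 13.1 and 12.8 and then 9.68 and 0.268. NFATC1, a calcium-activated transcription factor, was at 0.356 and 0.688 and then at 6.49 and 21.9. CD3D stood at 361.5 and 1076 in the simulated microgravity libraries that gave these receptor levels.

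Secreted factors and the receptors and targets of cytokine signalling were lower as lists. Of 15 cytokine and chemokine genes 14 were lower in both donors (medians -0.64 and -5.62), and camera called the list lower (adjusted p = 0.0257, and adjusted p = 0.759 with an estimated correlation). CCL3, a chemokine that draws monocytes and lymphocytes and the most abundant member (chromosome 17, 36088256 to 36090169), was at 3505 and 3335 in normal gravity and at 2202 and 0 in simulated microgravity. CCL4 was at 461.9 and 430.8 and then at 282.3 and 0, CCL5 at 418.7 and 419 and then at 267.5 and 0, and CSF1, a macrophage growth factor, at 45.8 and 58.5 and then at 29.8 and 0. The cytokine receptor and JAK-STAT list had 22 of 30 members lower in both donors and was called lower (medians -0.39 and -1.82; adjusted p = 0.045, and 0.759 with an estimated correlation). IL2RB, the receptor chain shared by IL-2 and IL-15, was at 294.3 and 296 and then at 178 and 0, and IL12RB2 at 26.3 and 32.6 and then at 19.9 and 0.0268. Immediate early genes (19 of 26 lower in both donors, medians -0.29 and -1.27, adjusted p = 0.0184) and NF-kB targets (16 of 21, medians -0.23 and -1.74, adjusted p = 0.0184) were also called lower, and with an estimated correlation the adjusted p was 0.759 for each. DUSP5, a MAP kinase phosphatase, was at 329.3 and 346.8 and then at 226 and 0.455, and BCL3, a co-regulator of NF-kB, at 62.1 and 68.8 and then at 45.3 and 0.348. CD69, an early activation marker of lymphocytes (chromosome 12, 9752486 to 9760901), went against its list, at 16.9 ± 0.0951 (SD, n = 2) in normal gravity and 48.3 ± 18.4 in simulated microgravity (log2 change 1.46, SE 0.33, adjusted p = 0.349). In these 4 lists 0 members passed over all genes or adjusted over the list alone (with the block, 1 JAK-STAT member over the list alone). The JAK-STAT call was also lost without ribosomal protein, mitochondrial and small RNA genes (adjusted p = 0.0681). The T cell gene CD3D was at 361.5 and 1076 in these simulated microgravity libraries.

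Transcription factors of the NK list went both ways. Of 23 factors on the NK list, 12 were lower and 9 higher in both donors, the medians were -0.29 and -0.59, and camera, which weighs the size of the changes, gave the higher direction without a call (adjusted p = 0.69). PRDM1, a factor of effector lymphocytes, was at 49.8 and 49.9 in normal gravity and at 34.7 and 0.0535 in simulated microgravity, and TOX2 at 476.3 and 456.9 and then at 295.2 and 2.03. TCF7, a factor of early T cell development (chromosome 5, 134114711 to 134151865), was at 0.024 and 0.0562 and then at 111 and 348.9 (adjusted p = 0.139). LEF1, its relative (chromosome 4, 108047545 to 108168956), was at 0.0704 and 0.26 and then at 168.3 and 485.7 (adjusted p = 0.139, and 0.0798 with the block). TCF7 and LEF1 are the 2 members that passed adjusted over the list alone (3 members with the block).

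**Figure D2:**
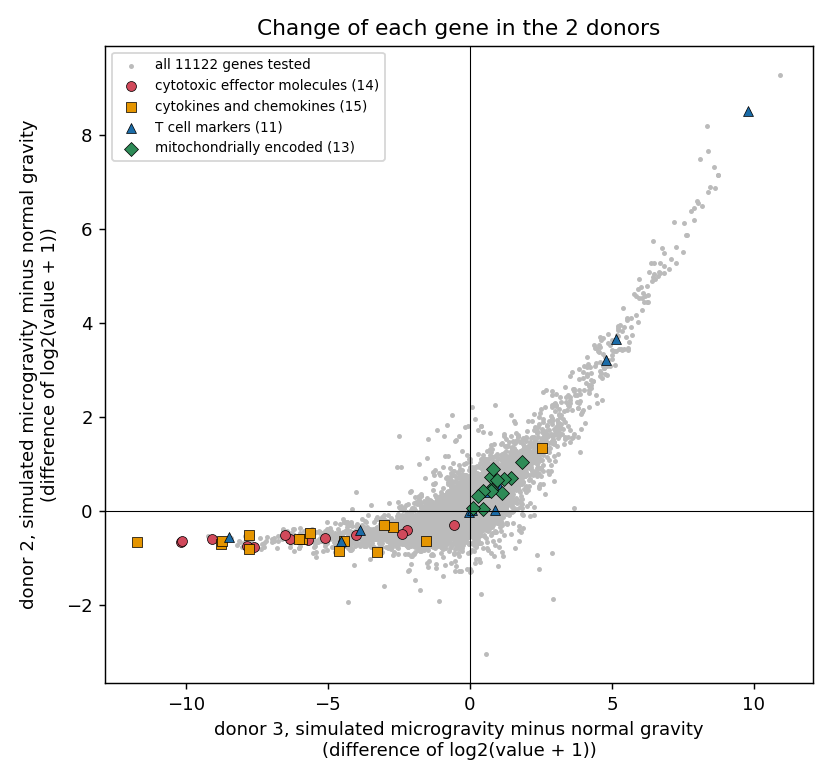
Difference of log2(value + 1) between simulated microgravity and normal gravity for each of the 11122 genes tested, donor 3 on the horizontal and donor 2 on the vertical axis, with 4 gene lists coloured. Cytotoxic effector genes spread widely along the donor 3 axis (median -6.02) at nearly constant donor 2 values (median -0.61), while among higher genes both donors' values increase together, up to 9.27 in donor 2 and 10.93 in donor 3 for ITM2A.

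Cytoskeletal genes, the usual candidates for a response to unloading, moved in 2 directions. The actin list was called lower (24 of 40 members lower in both donors, medians -0.19 and -0.69, camera adjusted p = 0.045) and the list of tubulins and microtubule motors higher (14 of 22 higher in both, medians 0.20 and 0.62, adjusted p = 0.0174). Neither call held with an estimated correlation (adjusted p = 0.759 for each), and the actin call was lost without the donor 3 simulated microgravity library (adjusted p = 0.0507), at a minimum mean value of 5 (0.0555) and without ribosomal protein, mitochondrial and small RNA genes (0.0681). COTL1, an actin-binding protein, was at 1572 and 1657 in normal gravity and at 1076 and 85.6 in simulated microgravity. CORO1A, which remodels actin at the immune synapse, was at 354.9 and 502.6 and then at 297.6 and 96.9. DOCK8, a regulator of actin whose loss impairs NK cells, was at 272.9 and 268.8 and then at 176.7 and 49.7. TUBA1A, an alpha tubulin, was at 85.0 and 71.5 and then at 126.8 and 241.7. STMN3, a stathmin that destabilises microtubules, was at 0.563 and 0.428 and then at 12.1 and 39.4 (adjusted p = 0.192), and 3 of the 22 tubulin list members passed adjusted over the list alone (0 with the block). Mechanosensing and nuclear envelope genes had medians of -0.01 and -0.48 (9 of 19 lower in both donors, adjusted p = 0.382), with ZYX, a focal adhesion protein, at 158.3 and 157.8 and then at 113.1 and 3.29. Adhesion and migration genes had 13 of 25 lower and 9 higher in both donors (medians -0.10 and -0.75; camera in the higher direction, adjusted p = 0.756). NCAM1, the NK marker CD56, was at 105.4 and 105.7 and then at 67.5 and 0. PECAM1, an adhesion molecule of several blood lineages, was at 0.0235 and 0.167 and then at 38.3 and 97.2, and it was 1 of 2 adhesion genes, both higher, that passed adjusted over the list alone. CD3D was at 361.5 and 1076 in the simulated microgravity libraries that gave these cytoskeletal values.

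Mitochondrially encoded genes were higher in simulated microgravity, and this was the list with the smallest p. All 13 were higher in both donors (medians 0.47 and 0.75; camera adjusted p = 0.000321, 0.759 as the adjusted p with an estimated correlation), 0 passed over all genes and 9 passed adjusted over the list alone (0 with the block). MT-CO1, a subunit of respiratory complex IV (mitochondrial genome, 5904 to 7445), averaged 4354 ± 321 (SD, n = 2) in normal gravity and 12330 ± 5510 in simulated microgravity (log2 change 1.43, SE 0.36, adjusted p = 0.349). Mitochondrial transcripts made up 3.77% and 3.83% of the normal gravity libraries and 5.72% and 7.86% of the simulated microgravity libraries (donors 2 and 3). The nuclear genes of oxidative phosphorylation did not follow (medians -0.14 and 0.04; 11 of 51 higher and 23 lower in both donors; adjusted p = 0.69). ATP5F1C was at 212 and 202.3 and then at 355.7 and 711.7, and NDUFB5 at 367 and 344.8 and then at 271.9 and 183.7. Cytosolic ribosomal proteins were called higher (adjusted p = 0.0257), but the medians were -0.06 in donor 2 and 0.45 in donor 3. That call was lost with the block (adjusted p = 0.0529), with quantile normalization (0.511), without the donor 3 normal gravity library (0.658), without the donor 3 simulated microgravity library (0.342) and with an estimated correlation (adjusted p = 0.759). RPL8 was at 814.6 and 732.2 and then at 1056 and 1828. The T cell gene CD3D was at 361.5 and 1076 in the same libraries. Against the mixture described below, the donor 2 median of the mitochondrially encoded list was 0.14. Most of its rise in donor 2 therefore cannot be told apart from a changed share of NK cell RNA.

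Glycolysis, hypoxia, sterol, cell cycle and proteasome lists were not called. Glycolysis genes had 10 of 21 members higher and 10 lower in both donors (adjusted p = 0.69). ENO2, an enolase most abundant in neurons, was at 0.118 and 0.135 in normal gravity and at 34.1 and 98.7 in simulated microgravity (adjusted p = 0.139, the single member that passed adjusted over the list alone, 3 with the block). PKM, the pyruvate kinase of proliferating cells, was at 3078 and 3428 and then at 2191 and 471.3. Hypoxia genes had 7 of 20 higher and 7 lower (adjusted p = 0.69), with DDIT4, an inhibitor of mTOR signalling, at 283.4 and 316.3 and then at 208 and 28.2. Cholesterol synthesis had 9 of 24 higher and 12 lower (adjusted p = 0.655), with SQLE at 39.6 and 39.0 and then at 101.2 and 208.6. Cell cycle genes had 25 of 44 higher and 13 lower (medians 0.12 and 0.11; adjusted p = 0.243). PCNA, the DNA polymerase clamp, was at 932.5 and 901.6 and then at 1365 and 2369, and CENPF, a kinetochore protein of dividing cells, at 336.6 and 402 and then at 260.6 and 141. The proteasome list had 12 of 36 higher and 17 lower (adjusted p = 0.69), with PSMA6 at 327.2 and 313.8 and then at 498.4 and 878.2. Replication-dependent histones had 6 of 13 lower and 1 higher in both donors (adjusted p = 0.167), with H1-2 at 129.1 and 103.7 and then at 75.6 and 16.7.

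Stress responses gave a single list call. The unfolded protein and integrated stress response list was called lower (18 of 28 members lower in both donors, medians -0.22 and -0.51, camera adjusted p = 0.0496). The adjusted p was 0.0529 with the block and 0.759 with an estimated correlation. It was also lost without either normal gravity library (0.0741 and 0.0811 for donors 2 and 3), without the donor 3 simulated microgravity library (0.0507), with quantile normalization (0.0783), at a minimum mean value of 5 (0.0555) and without ribosomal protein, mitochondrial and small RNA genes (0.0702). XBP1, a transcription factor of the unfolded protein response, was at 698.2 and 772.9 in normal gravity and at 534.6 and 122.4 in simulated microgravity. Adjusted over the list alone 1 member passed, in the higher direction. CEBPB was at 291.8 and 298.7 and then at 185.5 and 11.2. In the same simulated microgravity libraries CD3D stood at 361.5 and 1076 and NKG7 at 1444 and 0.947. Heat shock genes had 13 of 23 higher in both donors (medians 0.19 and 0.34; adjusted p = 0.0792), and HSPB1, a small heat shock protein, was listed at 0 in both normal gravity libraries and at 28.6 and 84.0 in simulated microgravity. The p53 and apoptosis list had 13 of 27 higher and 10 lower (adjusted p = 0.69), with TNFRSF10B, a TRAIL receptor, at 25.1 and 32.4 and then at 21.3 and 5.18. Interferon-stimulated genes had 15 of 37 higher and 14 lower (medians 0.08 and -0.16; adjusted p = 0.655), with TRIM22 at 0.354 and 0.186 and then at 19.2 and 50.3 and HERC5 at 12.1 and 11.5 and then at 40.5 and 99.7; TRIM22 passed adjusted over the list alone (0 members with the block). Antioxidant genes were evenly split (8 of 21 each way; camera adjusted p = 0.655), and fry, which does not compare a list with other genes, gave them an adjusted p of 0.00951 in the higher direction. PRDX2, described above, was the 1 member that passed adjusted over the list alone (0 with the block). The long RNAs kept in the nucleus had 3 of 11 higher and 5 lower in both donors (adjusted p = 0.72), with NEAT1 at 74.4 and 74.1 and then at 69.9 and 8.20.

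Markers of other cells differed between lineages. Of 11 T cell markers, 7 were higher and 4 lower in both donors (medians 0.02 and 0.57; camera adjusted p = 0.103), and 3 passed adjusted over the list alone, with or without the block. TRBC2, a constant segment of the T cell receptor beta chain that shares sequence with its neighbour TRBC1 (chromosome 7, 142801041 to 142802748), was at 167.9 and 158.3 in normal gravity and at 1565 and 4477 in simulated microgravity (log2 change 4.02, SE 0.54, adjusted p = 0.198). CD5, a surface protein of T cells, was at 0.219 and 0.187 and then at 14.4 and 41.0. TRDC, the delta chain segment that NK cells also transcribe, was at 349.4 and 357.5 and then at 237.4 and 0. Fetal globin transcripts stood out among the 4 tested erythroid genes. HBG1 (chromosome 11, 5248079 to 5249859) was at 0.269 and 0.0186 and then at 43.9 and 129.6, and HBG2, its near-identical neighbour with which it can share reads, at 0.029 and 0 and then at 21.5 and 76.3. Both fetal globin genes and AIF1 passed adjusted over their lists alone. HBD did not follow, at 1.97 and 0.966 and then at 0.791 and 0.661. Of the 3 tested monocyte and dendritic cell markers, AIF1 was at 3.17 and 2.96 and then at 153.5 and 453, while TYMP was at 10.3 and 12.8 and then at 6.94 and 1.39 and S100A9 at 3.26 and 2.30 and then at 1.38 and 0.0803. Of the 3 tested B and plasma cell markers, MZB1 was at 69.1 and 66.5 and then at 116.6 and 231.4 and CD79A at 2.14 and 1.17 and then at 0.619 and 0.669. Innate lymphoid and CD56bright markers had 7 of 9 lower in both donors (medians -0.55 and -2.28; adjusted p = 0.563), with XCL2 at 319.9 and 267.9 and then at 180.1 and 0.241. CAPG, an actin-capping protein and the 1 member that passed adjusted over the list alone, was at 1.57 and 2.42 and then at 32.04 and 87.75. Platelet and granulocyte lists had 0 members among the tested genes.

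**Figure D3:**
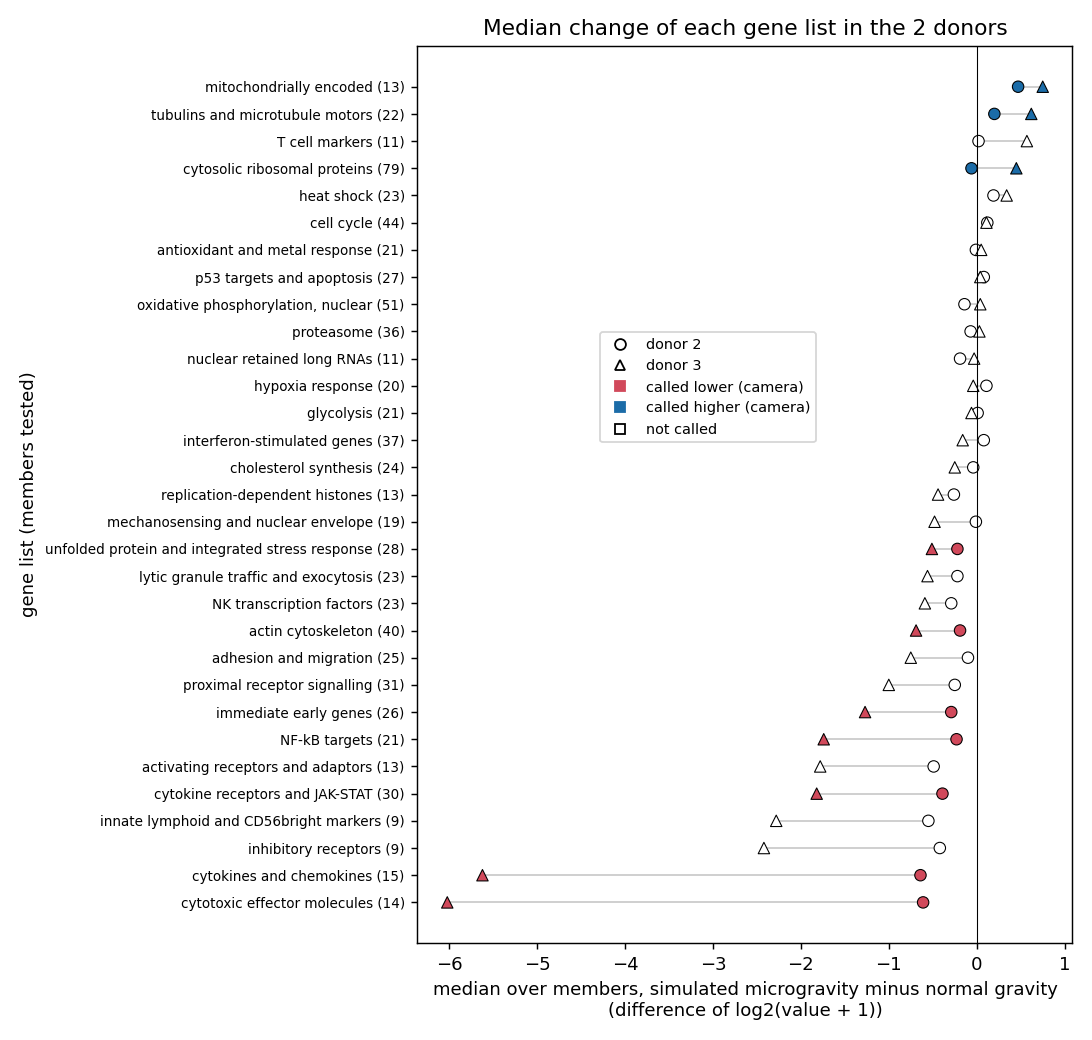
Median difference of log2(value + 1) between simulated microgravity and normal gravity over the members of each of 31 gene lists, for donor 2 (circles) and donor 3 (triangles), with lists called lower by camera in red, called higher in blue and not called in white. Donor 3 medians reach -6.02 for cytotoxic effector genes where the donor 2 median is -0.61, and mitochondrially encoded genes are higher in both donors (0.75 and 0.47).

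Single transcripts, like single genes, did not pass. limma called 0 of 22028 transcripts, with 1776 at an unadjusted p under 0.05. With the donor block 6 were called higher and 0 lower, and without an intensity trend 4 were called higher. Among the largest changes with the same sign in both donors, none past the threshold, a CD3D transcript was listed at 0 in both normal gravity libraries and at 311.3 and 964.7 in simulated microgravity (adjusted p = 0.385), and those of ITM2A and PRDX2 were likewise listed at 0 and then at 549.4 and 1858 and at 74.0 and 211.1. In the lower direction a DUSP28 transcript was at 8.05 and 6.52 and then at 0.334 and 0.0118 (adjusted p = 0.509), a WDR45 transcript at 4.35 and 0.817 and then at 0.048 and 0.0138, and an SRSF10 transcript at 4.35 and 1.35 and then at 0.197 and 0.0579. These low transcript values depend on how reads were divided among the transcripts of a gene.

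The 2 donors' changes were alike in direction and unlike in size. Across the 11122 genes the donors' simulated microgravity minus normal gravity differences had a Pearson r of 0.634 and a Spearman rho of 0.731 on the deposited scale, and 77.3% of genes had the same sign; the donors share no library, and genes are not independent replicates, so no p is given. The standard deviation of the differences was 1.33 in donor 2 and 2.39 in donor 3. The relation bent rather than scaled, as the plot of the change of each gene in the donors shows. NKG7 in donor 3 simulated microgravity stood at 0.00043 times its normal gravity level and RAB27A at 0.0479 times, yet donor 2 listed them at 0.64 and 0.591 times.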

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

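The counts of 0 called genes and 0 called transcripts stayed at 0 with other filters on low values, with 1 or 10 added before the logarithm, and with quantile normalization or median centring. A fold threshold, tried for genes alone, also left 0. Without an intensity trend 9 genes and 4 transcripts (of CD3D, PRDX2, ITM2A and LAPTM4B, named because they were called) were higher, the genes all being listed at 0 in both normal gravity libraries. The donor block alone gave 0 genes and 6 transcripts higher, and the block with 1 added before the logarithm, a setting chosen after seeing the data, gave 3 genes (ESD, MTND1P23 and MTND4P12, named because they were called) and 50 transcripts higher. The last 2 genes are pseudogene copies of mitochondrial genes and can share reads with them. Leaving out 1 library at a time gave 0 to 2626 genes higher and 0 to 3341 lower, with the lone library assumed to vary like the other group, and the largest counts came without the donor 2 simulated microgravity library. Of 153 genes named by the rule, 0 changed direction when 1 simulated microgravity library was left out. The rule took nearly all of them for the same sign in both donors, so this was largely fixed beforehand. Of the lists, 3 higher and 7 lower in the main test, 1 and 4 stayed called without ribosomal protein, mitochondrial and small RNA genes (29 lists) and 0 and 0 with an estimated correlation. By fry, 1 list was higher, antioxidant and metal response, which the main test had not called, and 0 were lower. Leaving out 1 library gave 2 to 5 lists higher and 6 to 13 lower. The donor block gave 2 and 6, losing the ribosomal and the unfolded protein response lists, and changed no other list call. The donors' correlation of 0.634 was 0.747 with 1 added, 0.792 with 10 added and 0.549 with quantile normalization. The cause was not tested, except where fewer genes or fewer libraries made the alternative. Genes listed under 0.5 numbered 222, 205, 12 and 263 in the 4 libraries. Those low values rest on few reads, so the size of a fold change is imprecise. The same gene could still be abundant in the other group, as ITM2A was, at 0 in both normal gravity libraries and 615.5 and 1944 in simulated microgravity.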

Other observations

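Genes of early T cell development and of T-lineage leukaemia were on balance higher in simulated microgravity. This list was added after T cell genes had been seen to be high, and was drawn up before the values of its members, TAL1 among them, had been looked at. Of 14 members 10 were higher and 3 lower in both donors, with medians of 2.54 and 3.64 (donors 2 and 3), and the list had no test against other genes. Listed genes absent from the deposited table were not counted. Members nearly absent in normal gravity, such as SOX4 and TAL1, passed the filter only through their simulated microgravity levels. This selection favours higher members in the count and the medians. ADA, the adenosine deaminase abundant in thymocytes, was at 3.61 and 4.05 in normal gravity and at 443 and 1300 in simulated microgravity. MYB, a transcription factor of blood progenitors, was at 7.37 and 9.62 and then at 204 and 578, and SOX4, a factor of early lymphocytes, at 0.117 and 0.0929 and then at 131 and 386. CD99, a surface protein of thymocytes, was at 320 and 312 and then at 424 and 694. NOTCH1, the receptor that commits progenitors to the T lineage, was at 5.1 and 5.99 and then at 25.7 and 68.1. These 5 members, all higher, were picked from the list after their values were seen. The 3 lower members were CD38, MEF2C and TRIB2. CD38 was at 219 and 211 and then at 163 and 72.5, MEF2C at 8.11 and 6.67 and then at 4.29 and 1.02. TRIB2 was at 34.1 and 34.3 and then at 31.7 and 13.6.

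A second added list, of erythroid and myeloid leukaemia genes, shared TAL1 and MYB with the first and gave a mixed result. Of its 13 members 6 were higher and 5 lower in both donors (medians 0.05 and 0.6). TFRC, the transferrin receptor of dividing and red precursor cells, was at 102 and 110 in normal gravity and at 201 and 384 in simulated microgravity. LYN, a kinase of myeloid and NK cells, was at 226 and 246 and then at 152 and 2.55, and GYPC, a red cell membrane protein, at 159 and 166 and then at 108 and 8.51. These members too were picked after their values were seen.

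All 14 tested cytotoxic effector genes were lower in both simulated microgravity libraries, and of 11 T cell markers 7 were higher and 4 lower in both. The tests of this pattern were chosen after seeing the result, except for the test of the added T-lineage list. The bound of that test was written before its members' values were computed. RNA of a second, T-lineage population would make donor 2 lose the same share of every first-profile gene that it gains of every second-profile gene. The 113 genes abundant in normal gravity and nearly absent in donor 3 simulated microgravity stood in donor 2 at a median of 64.9% of their normal gravity level. The 88 genes nearly absent in normal gravity reached 34.2% of the donor 3 level, and the shares summed to 0.991. Both sets were chosen by level alone, so a second population of any lineage would give this sum. The added list's smaller median of 2.54 was above the bound of a population carrying immature T cell or T-lineage leukaemia genes. However, T cell genes had prompted the list, and some members passed the filter only through simulated microgravity, so this result carries little weight. Leukaemic target cells stay an untested hypothesis, since the labels do not say whether cells had met targets and name no sort or gate. A response proportional on the log scale was not met. The 133 genes more than 32-fold lower in donor 3 were lower in donor 2 by 0.63 less than predicted (95% interval over genes 0.55 to 0.69). Scaling between libraries was not met either, because the cytotoxic median in donor 2 was still -0.6 after quantile normalization. A wrong label on 1 library alone was not met as the source of the whole pattern. The second profile was also present in donor 2 (median 29 against 0.0848 in normal gravity), and so in 2 simulated microgravity libraries. That profile was chosen by the donor 3 and the normal gravity libraries, so its presence in donor 3 was fixed beforehand. A wrong label on the donor 3 library, beside a mixed donor 2 library, could therefore not be excluded. A switch of a share of the NK cells to the second profile under simulated microgravity would give the same values and was not tested.

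Donor 2's simulated microgravity library was then compared with a mixture of 65.8% of its normal gravity profile and 34.2% of the donor 3 simulated microgravity profile. The prediction on the spread was written before its value was computed, and the test of the cytotoxic list was chosen after seeing the result. The spread of genes (robust SD) around the mixture was 0.157, against 0.347 between the donor 2 libraries. It was 0.755 times the 0.208 between the normal gravity libraries, with 48 genes more than 2-fold from the mixture against 93 between those libraries. The mixture held donor 2's own normal gravity profile and took its share from the tested library. The normal gravity libraries came from different donors, so a low ratio was favoured. Mixing alone could account for most of the donor 2 difference, but the ratio does not show that nothing else differed. A fall of cytotoxic genes beyond dilution was not met, their median against the mixture being -0.04 (95% interval over members -0.09 to 0.0), although this cannot exclude an effect in donor 3, whose NK genes were almost absent. Small departures remained in ribosomal proteins (-0.14, 78 of 79 below the mixture), nuclear oxidative phosphorylation genes (-0.11, 48 of 51 below) and mitochondrially encoded genes (0.14, 11 of 13 above), where the 2 normal gravity libraries differed by -0.2, -0.14 and 0.03.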
